A study of Homo sapiens with 26 samples.

How the data were processed

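RNA sequencing had been done on 26 libraries, 2 for each of 13 groups of A375 and NOMO-1 cells. Per the labels, parental and tolerant cells were treated with DMSO or CPI203, A375 cells for 6 h and NOMO-1 cells for 24 h, and A375 cells were also taken untreated at 0 h. The protocol names TRIzol and RNeasy for the extraction of RNA, without saying which was used for which library. According to the submitters' processing notes, reads were aligned to hg19 with TopHat 1.4.1 and expression was estimated with Cufflinks. The Cufflinks version and options, the annotation release and the strandedness of the libraries are not given in the sources used here. The values in the deposited table are FPKM, estimated per gene by the authors with Cufflinks, with a gene symbol, an Ensembl identifier and hg19 coordinates for each gene. The table holds no read counts or library sizes, so counting error could not be computed and the depth is unknown. Values for 36 genes are missing in NOMO-1 columns, and these genes were not used in the NOMO-1 fit.

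Groups were taken from the sample titles. For the 4 untreated clone libraries 1 label field says parental, and the title, which names the clone, was followed. FPKM values were put on a log2 scale after adding 1. Genes at 1 FPKM or more in at least 2 libraries of the fit were kept, 16935 for A375 and 16753 for NOMO-1. Linear models with a mean for each group were fitted with limma 3.58.1 in R 4.3.3, with the trend and robust options, to all 18 A375 libraries (9 groups, 9 residual and a median of 3.43 prior degrees of freedom) and all 8 NOMO-1 libraries (4 groups, 4 residual and a median of 4.88 prior). All tests are two-sided. P-values were adjusted by the Benjamini-Hochberg method over all genes of a comparison, and a gene passed at an adjusted p below 0.05. The 14 planned comparisons are CPI203 against DMSO in each of the 5 cell populations, the difference of that effect between tolerant and parental cells for each clone and for NOMO-1, tolerant against parental cells in DMSO and, for A375, untreated, and DMSO against untreated parental A375 cells. After the data were seen, 2 more were added: DMSO against untreated cells of clones 1 and 4.

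Named genes followed a rule set before the data were examined. They are genes of the BET, BCL2 and cell cycle machinery, up to 6 genes with the largest rise and 6 with the largest fall among those that passed, had a mean of at least 5 FPKM in the higher group and no overlap between the libraries of the groups (a condition not applied to differences of effects), and up to 4 members with the smallest adjusted p of each list described. Genes of chromosome Y and XIST were left out, and some genes that the rule names are not reported here. Genes outside the rule are said to have been chosen after their values were seen.

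Set at the same time were 32 gene lists: anti-apoptotic, BH3-only and effector BCL2 genes, caspases and death receptors, BET family and P-TEFb, MYC family and targets, polyadenylated histones, E2F targets, mitosis, G1 regulators, p53 targets, NF-kB and cytokines, interferon response, AP-1 and immediate early genes, ATF4 and unfolded protein response, heat shock, hypoxia and glycolysis, cholesterol and fatty acid synthesis, ribosomal proteins, MAPK output, WNT, NOTCH and hedgehog, melanocyte lineage, dedifferentiated melanoma and receptor kinases, epithelial-mesenchymal and matrix genes, MLL-fusion program, myeloid markers, multidrug and drug metabolism genes, and markers of epithelial, fibroblast and endothelial, erythroid and megakaryocytic, and lymphoid cells. Each was tested with camera in limma against all other genes, with a preset correlation of 0.01 and again with the correlation estimated, and adjusted over the lists of a comparison. Of 434 tests in the planned comparisons 110 passed with the preset correlation, and 13 of these with the estimated one. Lists with fewer than 2 measured members were not tested, which left out fibroblast markers in NOMO-1 and lymphoid markers in A375.

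Alternatives tried were a pseudocount of 0.1, no filter and a filter at 5 FPKM, quantile normalization, median-ratio scaling, limma without trend and robust options, the replicate number as a block, only the compared libraries in the fit, an absolute log2 change of at least 1, and leaving out each replicate in turn. Chosen after seeing the data were the omission of 3 A375 libraries that stand apart and a correction of each library for its trend over transcript length and GC content. That correction used GENCODE release 29, matched by Ensembl identifier and available for 96.99% of the A375 and 96.8% of the NOMO-1 genes fitted, with Biostrings 2.70.1; coordinates came from the deposited table. In simulated data with 50 genes changed per size, the model recovered 84% of 2-fold changes in the A375 parental CPI203 layout. For the clone 1 difference of effects it was 56%, and in the like NOMO-1 layouts 88% and 72%. With unequal spread, as here, rates may differ. Figures were drawn with matplotlib 3.10.9.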

Results

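RNA sequencing measured gene expression in 26 libraries from cultures of A375, an established human melanoma cell line with mutant BRAF, and NOMO-1, an established human acute myeloid leukaemia line. The libraries fall into 13 groups of 2. For each line there were parental cells and cells derived to tolerate BET bromodomain inhibition, which the sample titles call resistant: clones 1 and 4 of A375, and 1 tolerant NOMO-1 population. BET proteins read acetylated histones at active genes, and CPI203 is a small molecule that blocks their bromodomains. A375 cells were harvested untreated (0 h) or after 6 h with DMSO or 1 uM CPI203. NOMO-1 cells were harvested after 24 h with DMSO or 1 uM CPI203. The values are FPKM, which scale the fragments of a gene to the length of its transcript and to all mapped fragments. Read counts were not used, so library depth is unknown. FPKM summed to 501933 to 637916 in the 18 A375 libraries, with 14662 to 15483 genes at 1 FPKM or more. In the 8 NOMO-1 libraries the sums were 417391 to 488682, with 14433 to 15358 such genes. The 4 untreated clone libraries, parental in 1 label field, were grouped by their titles, which name the clone. The A375 24 h treatment named in the protocol is not analysed here.

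In 3 A375 libraries the values lay further from those of the other replicate than elsewhere: parental DMSO replicate 1, clone 4 DMSO replicate 1 and clone 4 CPI203 replicate 2. The median absolute log2 difference between replicates was 0.220, 0.293 and 0.231 in their groups, against 0.0607 to 0.116 in the other 6 A375 groups and 0.0741 to 0.174 in NOMO-1. Small structured RNA made up 0.477% of FPKM in parental DMSO replicate 1 and at most 0.274% in any other library. The 4 untreated clone libraries had GAPDH as their top gene, at 6362 to 8344 FPKM. Changes below are log2 differences of FPKM + 1 with their standard error from limma. Levels are mean FPKM ± SD, with n = 2 libraries per group. The labels do not say that the replicates were separate cultures, so the p-values measure only the spread between libraries, which may be technical in part. Differences between values below 1 FPKM are compressed by the added 1. Lists of genes were fixed before the data were examined and tested with camera. After the members of a list that rose and fell over all genes, brackets give these counts with p adjusted over the list alone, then the adjusted p of camera, and where it passed also that with the correlation between members estimated.

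Among the genes chosen beforehand for naming are, with hg19 positions, MYC (ENSG00000136997, chr8 128747680 to 128753674), HEXIM1 (ENSG00000186834, chr17 43224684 to 43229468), BRD2 (ENSG00000204256, chr6 32936437 to 32949282) and BRD3 (ENSG00000169925, chr9 136895427 to 136933657). From the BCL2 family they are BCL2 (ENSG00000171791, chr18 60790579 to 60987361), BCL2L1 (ENSG00000171552, chr20 30252255 to 30311792), MCL1 (ENSG00000143384, chr1 150547032 to 150552066) and BCL2A1 (ENSG00000140379, chr15 80253231 to 80263788). The BH3-only genes are BCL2L11 (ENSG00000153094, chr2 111876955 to 111926024), BMF (ENSG00000104081, chr15 40380091 to 40401093), BBC3 (ENSG00000105327, chr19 47724081 to 47736023), PMAIP1 (ENSG00000141682, chr18 57567180 to 57571538) and BID (ENSG00000015475, chr22 18216906 to 18257536). Further ones are BAX (ENSG00000087088, chr19 49458072 to 49465055), BAK1 (ENSG00000030110, chr6 33540329 to 33548019) and CDKN1A (ENSG00000124762, chr6 36644305 to 36655116).

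The first question was what 6 h of CPI203 does to parental A375 cells. HEXIM1, which holds the elongation factor P-TEFb inactive, rose from 19.8 ± 0.359 to 61.1 ± 1.09 FPKM (SD, n = 2; 1.58 ± 0.09, adjusted p = 9.84e-08). BRD2, itself a BET protein, rose from 75.6 ± 5.55 to 187 ± 3.78 FPKM (1.30 ± 0.11). PMAIP1, which encodes the BH3-only protein NOXA, rose from 11.6 ± 0.271 to 42.6 ± 2.59 FPKM (1.79 ± 0.09), and CDKN1A, the CDK inhibitor p21, from 74.1 ± 2.82 to 159 ± 4.82 FPKM (1.09 ± 0.12). BCL2L1, which encodes the survival protein BCL-XL, fell from 21.6 ± 0.493 to 13.3 ± 1.32 FPKM (-0.66 ± 0.08). MYC did not pass, at 9.61 ± 0.711 FPKM with CPI203 and 8.76 ± 0.155 with DMSO (0.12 ± 0.11, adjusted p = 0.405). Of 16935 genes tested, 6160 passed: 2543 rose (41.3%, but 50.02% with quantile normalization and 52.1% after the length and GC correction) and 3617 fell, 344 and 662 of them by at least 1 on the log2 scale.

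Within the BCL2 family, the BH3-only gene BCL2L11 (BIM) rose (0.72 ± 0.13), while BID (-0.51 ± 0.12), BBC3, which encodes PUMA (-0.67 ± 0.23), and the pore-forming effector BAX (-0.65 ± 0.17) fell. Without CPI203 replicate 1 BID did not pass (-0.42), nor BAX without DMSO replicate 1 (-0.49) or CPI203 replicate 2 (-0.61). BMF (-0.02 ± 0.10), BAK1 (-0.13 ± 0.14), BCL2 (-0.09 ± 0.18), MCL1 (0.29 ± 0.13), BCL2A1 (0.33 ± 0.15) and BRD3 (0.04 ± 0.21) did not pass. The largest rises among genes at 5 FPKM or more were RP11-655M14.13 (ENSG00000255318, chr11 67385750 to 67394775; 2.94 ± 0.18), CTGF, a matricellular target of YAP (ENSG00000118523, chr6 132269316 to 132272513; 2.90 ± 0.08, from 9.14 ± 0.379 to 74.6 ± 0.806 FPKM) and the histone gene HIST1H2BD (ENSG00000158373, chr6 26158349 to 26171577; 2.80 ± 0.13). They were followed by TBX10 (ENSG00000167800, chr11 67398774 to 67407031; 2.75 ± 0.11), WNT9A (ENSG00000143816, chr1 228106357 to 228135631; 2.69 ± 0.10) and SAT1, a polyamine-degrading enzyme (ENSG00000130066, chrX 23801290 to 23804343; 2.62 ± 0.11). The largest falls were TRAF1, an NF-kB signalling adaptor (ENSG00000056558, chr9 123664671 to 123691451; -3.43 ± 0.09), the transcription factor TFAP2B (ENSG00000008196, chr6 50786436 to 50815326; -3.43 ± 0.11) and the retinoid receptor RXRG (ENSG00000143171, chr1 165370159 to 165414433; -2.99 ± 0.09). Next came B3GNT7 (ENSG00000156966, chr2 232260254 to 232265875; -2.99 ± 0.10), the cytokine IL1A (ENSG00000115008, chr2 113531492 to 113542167; -2.96 ± 0.11) and FST, an activin antagonist (ENSG00000134363, chr5 52776239 to 52782964; -2.85 ± 0.13).

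Among polyadenylated histone genes, 13 of 15 rose and 0 fell (14 and 0 alone, adjusted p = 1.65e-11, adjusted p = 0.0853 with an estimated correlation). Of the E2F target genes of DNA replication, 1 of 30 rose and 22 fell (1 and 22 alone, adjusted p = 2.2e-06, adjusted p = 0.0416 with an estimated correlation). The replication helicase genes MCM2 (-1.44 ± 0.08), MCM5 (-1.30 ± 0.09) and MCM3 (-0.89 ± 0.07) and the regulator E2F2 (-1.42 ± 0.09) were among those that fell. In the NF-kB and cytokine list, 0 of 24 rose and 11 fell (0 and 11 alone, adjusted p = 0.000968, adjusted p = 0.0416 with an estimated correlation), with LIF at -2.40 ± 0.12, IL8 at -1.25 ± 0.09 and NFKB1 at -1.15 ± 0.09. Of the interferon-response genes, 2 of 23 rose and 12 fell (3 and 12 alone, adjusted p = 0.0163, adjusted p = 0.0853 with an estimated correlation). The antiviral sensors OAS1 (-1.50 ± 0.13) and OAS2 (-1.25 ± 0.13) fell and the transcription factor IRF7 rose (1.82 ± 0.19). Among AP-1 and immediate early genes, 8 of 19 rose and 0 fell (9 and 1 alone, adjusted p = 0.00091, adjusted p = 0.436 with an estimated correlation), with FOS at 1.996 ± 0.14, ZFP36 at 1.69 ± 0.13 and ATF3 at 1.32 ± 0.12. Of the cholesterol and fatty acid synthesis genes, 7 of 20 rose and 1 fell (7 and 1 alone, adjusted p = 0.0242, adjusted p = 0.332 with an estimated correlation), with LSS at 1.09 ± 0.10 and IDI1 at 0.91 ± 0.09. In the BET and P-TEFb list, 6 of 13 rose and 2 fell (7 and 2 alone, adjusted p = 0.0318, adjusted p = 0.53 with an estimated correlation). ELL2, an elongation factor, rose (1.43 ± 0.16) and HEXIM2 fell (-1.42 ± 0.16).

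The other lists did not pass in parental A375 cells. For MYC family and target genes, 2 of 30 rose and 10 fell (2 and 10 alone, adjusted p = 0.388). For p53 targets, 10 of 23 rose and 7 fell (11 and 7 alone, adjusted p = 0.281). The adjusted p was 0.813 for the anti-apoptotic BCL2 list, 0.675 for the BH3-only list, 0.503 for the effector list and 0.846 for caspases and death receptors. It was 0.846 for mitotic genes, 0.958 for G1 regulators, 0.813 for ribosomal proteins, 0.806 for MAPK output, 0.846 for WNT and 0.813 for NOTCH and hedgehog. Last, it was 0.651 for multidrug and drug-metabolising genes, 0.813 for epithelial-mesenchymal and matrix genes, and 0.312, 0.308 and 0.651 for epithelial, fibroblast and endothelial, and erythroid markers. With the compared libraries alone 3977 genes passed, and 4104 without CPI203 replicate 1. MYC and MCL1 passed after correction for transcript length and GC content (0.32 and 0.30), MCL1 also without DMSO replicate 2 (0.41), and BCL2A1 without the 3 libraries that stand apart (0.53). BBC3 did not pass with quantile normalization (-0.59), median-ratio scaling (-0.64), no filter (-0.67) or when any 1 of 3 libraries was left out (-0.54 to -0.77).

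**Figure D1:**
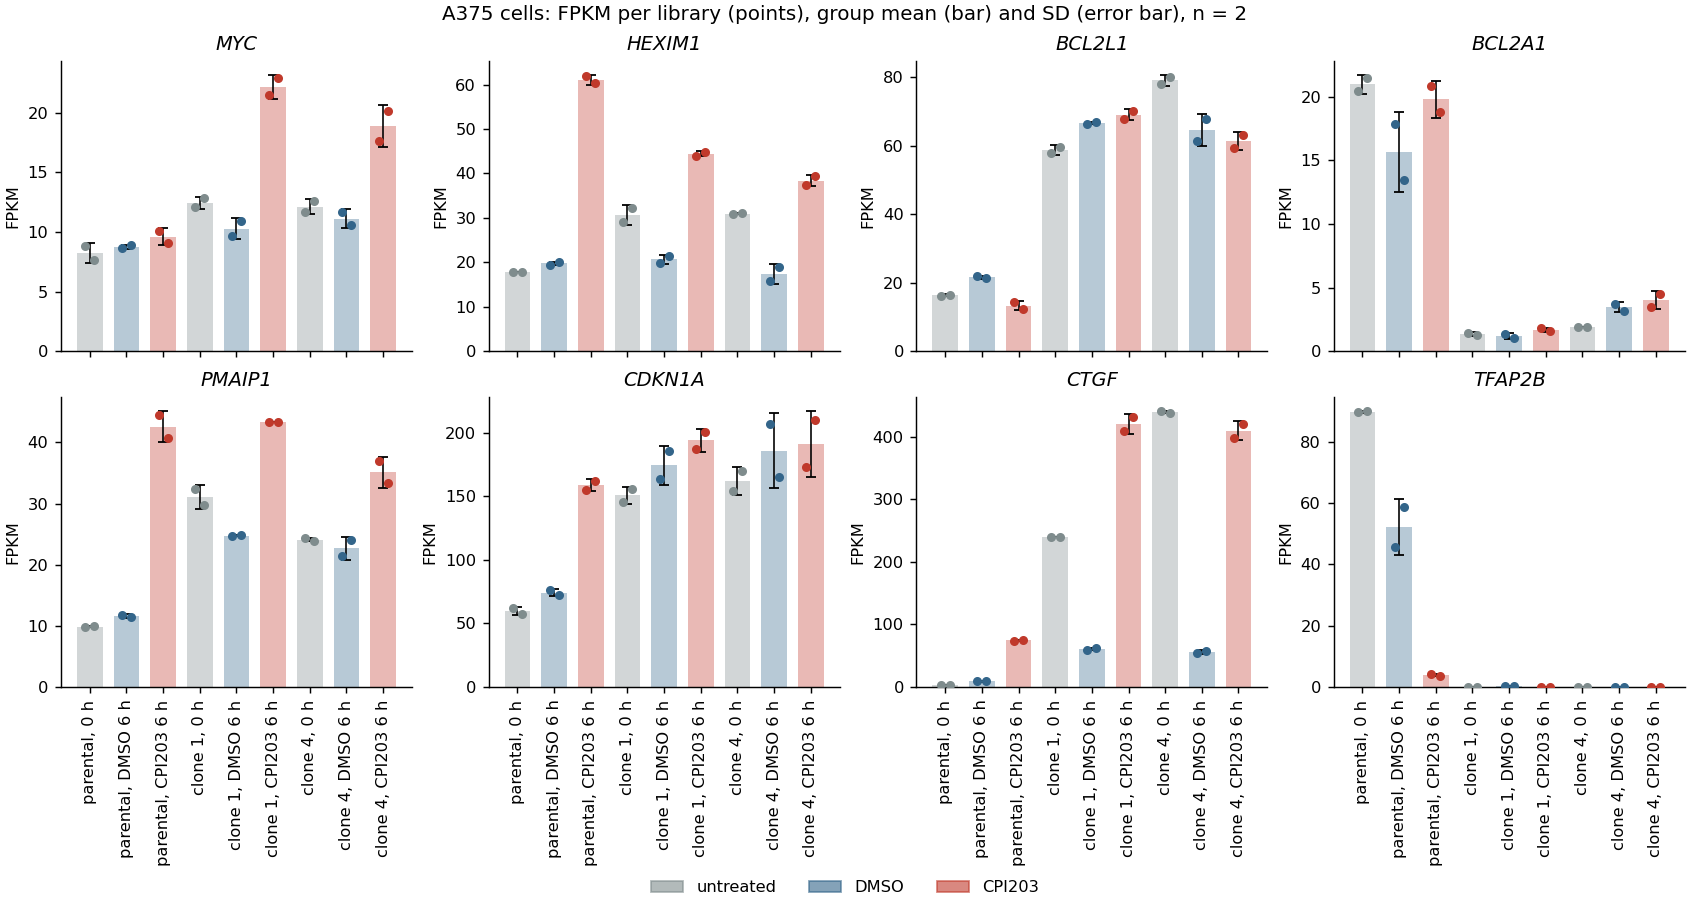
FPKM of MYC, HEXIM1, BCL2L1, BCL2A1, PMAIP1, CDKN1A, CTGF and TFAP2B in the 9 A375 groups (grey untreated 0 h, blue DMSO 6 h, red CPI203 6 h), with each library as a point, the mean as a bar and the SD of n = 2 as the error bar, on linear axes that start at 0. BCL2L1 averaged 21.6 FPKM in parental DMSO libraries and 66.6 and 64.5 in those of clones 1 and 4.

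The same treatment was then compared within each tolerant clone. HEXIM1 rose in clone 1 (1.07 ± 0.09) and clone 4 (1.11 ± 0.09), as did BRD2 (1.06 ± 0.11 and 0.995 ± 0.11). MYC rose from 10.3 ± 0.855 to 22.2 ± 0.999 FPKM in clone 1 (1.04 ± 0.11, adjusted p = 2.87e-05; SD, n = 2) and from 11.1 ± 0.822 to 18.9 ± 1.78 in clone 4 (0.71 ± 0.11, adjusted p = 0.00043). PMAIP1 (0.78 ± 0.09 and 0.61 ± 0.09) and BCL2L11 (0.69 ± 0.13 and 0.83 ± 0.13) rose, and BAX fell (-0.64 ± 0.17 and -0.74 ± 0.17), in clones 1 and 4 in that order. BAX did not pass when any 1 of 3 libraries in clone 1 (-0.53 to -0.69) or 2 in clone 4 (-0.54 and -0.51) was left out. BCL2L1 (0.05 ± 0.08 and -0.07 ± 0.08) and CDKN1A (0.16 ± 0.12 and 0.05 ± 0.12) did not pass in either, though CDKN1A did after the length and GC correction (0.26 and 0.23). In clone 1, 3733 genes passed, 1424 higher and 2309 lower. In clone 4, 3998 passed, 1500 higher and 2498 lower. The share that rose was 38.2% and 37.5%, but 47.2% and 48.2% with quantile normalization and 51.2% and 50.3% after the length and GC correction.

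CTGF rose in both clones, to 421 ± 16.02 FPKM in clone 1 (2.77 ± 0.08) and 409.9 ± 15.4 in clone 4 (2.85 ± 0.08). The largest falls in both were the adhesion receptor GPR110 (ENSG00000153292, chr6 46965440 to 47010099; -2.96 ± 0.16 and -2.87 ± 0.16) and FST (-2.47 ± 0.13 and -2.30 ± 0.13). Also among the 6 were the endothelial receptor ROBO4 (ENSG00000154133, chr11 124753587 to 124768396; -2.17 ± 0.16 and -2.27 ± 0.16) and the keratin KRT80 (ENSG00000167767, chr12 52562780 to 52585784; -2.06 ± 0.08 and -2.22 ± 0.08). The rises in clone 1 included DHRS2 (ENSG00000100867, chr14 24099324 to 24114848; 2.08 ± 0.12). Those in clone 4 included HIST2H2BE (ENSG00000184678, chr1 149856010 to 149858232; 1.91 ± 0.14). The near-identical histone copies HIST2H4A and HIST2H4B also rose and cannot be told apart by short reads.

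Polyadenylated histone genes moved together here too: 12 of 15 rose and 0 fell (12 and 0 alone, adjusted p = 3.88e-13, adjusted p = 0.214 with an estimated correlation) in clone 1. In clone 4, 12 of 15 rose and 0 fell (15 and 0 alone, adjusted p = 4.89e-14, adjusted p = 0.158 with an estimated correlation). In clones 1 and 4, 11 and 8 AP-1 genes and 7 and 8 cholesterol genes rose (adjusted p = 1.68e-06 and 0.000347, and 0.00131 and 0.000218), and 9 and 11 E2F targets fell (adjusted p = 0.019 and 0.0304). The ATF4 list passed upwards in clone 1 (adjusted p = 0.019) and the BET list in clone 4 (adjusted p = 0.0304). With an estimated correlation none of these passed (adjusted p from 0.158 to 0.44).

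The CPI203 responses of parental cells and clones overlapped. Of 16935 genes, 1158 rose in parental cells and clone 1, where independence would give 213.8, and 1988 fell in both, against 493.2. For clone 4 these counts were 1241 against 225.2 and 2098 against 533.5. The changes correlated across genes with Pearson r = 0.7998 for clone 1 and 0.811 for clone 4, and genes are not independent replicates. The 1006 genes that changed at least 2-fold in parental cells had a median absolute change of 1.24 there, and moved in that direction by a median of 0.78 in clone 1 and 0.81 in clone 4. Choosing them by their size in parental cells inflates the first of these medians. In clone 1, 7162 genes passed without the 3 libraries that stand apart and 6717 with the compared libraries alone. None of the 3 is from clone 1, whose gain over the full fit came from the spread. The fit pools that over all groups as if equal, although replicate differences were not. In clone 4 the count was 24 with the compared libraries alone (HEXIM1, BRD2, MYC, PMAIP1, BCL2L11 and BAX did not pass then).

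The clones' CPI203 effects were tested against those of parental cells. TFAP2B fell from 52.3 ± 9.13 to 3.91 ± 0.270 FPKM in parental cells (SD, n = 2) and was at or below 0.322 FPKM in both clones under DMSO, and the difference was 3.07 ± 0.15 for clone 1 and 3.33 ± 0.15 for clone 4. TRAF1 (2.75 ± 0.12 and 2.997 ± 0.12) and RXRG (2.55 ± 0.13 and 2.76 ± 0.13; 1.33 and not passing in clone 1 with a pseudocount of 0.1) also had less negative effects in the clones. So had the epithelial anchoring gene LAD1 (ENSG00000159166, chr1 201342372 to 201368736; 2.65 ± 0.13 and 2.66 ± 0.13) and the prostaglandin E synthase PTGES (ENSG00000148344, chr9 132500610 to 132515326; 2.66 ± 0.17 and 2.63 ± 0.17; 2.32 and not passing in clone 4 with that pseudocount). The DMSO levels of these 4 genes were 1.05, 0.426, 0.0485 and 0.0719 FPKM in clone 1. PMAIP1 rose less in the clones (-1.005 ± 0.12, adjusted p = 0.00057, and -1.18 ± 0.12, adjusted p = 0.000148), as did CDKN1A (-0.93 ± 0.17, adjusted p = 0.0147, and -1.04 ± 0.17, adjusted p = 0.00609). BCL2L1, which fell in parental cells, had a less negative effect in both clones (0.71 ± 0.12, adjusted p = 0.00549, and 0.59 ± 0.12, adjusted p = 0.0159). For MYC the difference passed in clone 1 (0.92 ± 0.15, adjusted p = 0.0052) and not in clone 4 (0.59 ± 0.15, adjusted p = 0.0637). HEXIM1 did not pass (-0.51 ± 0.13 and -0.47 ± 0.13) but did under 3 alternatives in clone 1 and 4 in clone 4. BCL2L1 in clone 4 did not pass without the 3 libraries that stand apart (0.45), and CDKN1A in clone 1 did not when any 1 of 5 libraries was left out (-0.84 to -0.98). With the compared libraries alone BCL2L1, CDKN1A, PMAIP1, GPR110 and MMP1 did not pass in clone 4. In clone 1, 324 genes differed, 236 with a higher and 88 with a lower effect than in parental cells, and in clone 4 388, of which 270 and 118.

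Among the lowest differences were those of GPR110 (-1.93 ± 0.22 and -1.85 ± 0.22, but -0.90 and -0.75 and not passing with a pseudocount of 0.1), SAT1 (-1.54 ± 0.16 and -1.74 ± 0.16) and DKK1 (ENSG00000107984, chr10 54074056 to 54077802; -1.56 ± 0.20 and -1.72 ± 0.20). Also among them were the stress kinase PLK2 (ENSG00000145632, chr5 57749809 to 57756087; -1.81 ± 0.18 and -1.60 ± 0.18) and the collagenase MMP1 (ENSG00000196611, chr11 102660651 to 102668891; -1.66 ± 0.18 and -1.54 ± 0.18). A member of a list rose here when its effect was higher in the clone. Of the E2F targets, 3 of 30 rose and 0 fell (9 and 0 alone, adjusted p = 2.91e-10, adjusted p = 0.0151 with an estimated correlation) for clone 1. For clone 4, 5 of 30 rose and 0 fell (8 and 0 alone, adjusted p = 1.49e-10, adjusted p = 0.0137 with an estimated correlation). In the NF-kB list, 5 of 24 rose and 0 fell (5 and 2 alone, adjusted p = 0.0018, adjusted p = 0.0387 with an estimated correlation) for clone 1. For clone 4, 5 of 24 rose and 2 fell (9 and 3 alone, adjusted p = 0.00262, adjusted p = 0.0513 with an estimated correlation), with LIF at 2.40 ± 0.17 and 1.79 ± 0.17 and IL1A at 2.31 ± 0.16 and 1.93 ± 0.16, the last not passing with a pseudocount of 0.1. Of the p53 targets, 0 of 23 rose and 3 fell (3 and 6 alone, adjusted p = 0.00304, adjusted p = 0.0861 with an estimated correlation) for clone 1. For clone 4, 0 of 23 rose and 3 fell (2 and 7 alone, adjusted p = 0.00262, adjusted p = 0.0586 with an estimated correlation). Histone genes had lower effects in the clones (adjusted p = 8.17e-05 and 0.00227), as had the BET and P-TEFb list in clone 1 (adjusted p = 0.0301), and the MAPK list had higher ones there (adjusted p = 0.0363). With an estimated correlation these gave adjusted p = 0.388, 0.495, 0.593 and 0.677. With the compared libraries alone, and no spread pooled from other groups, only 163 genes differed in clone 1 and 41 in clone 4.

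Clones and parental cells were compared first in DMSO at 6 h, with prior CPI203 exposure not stated. BCL2L1 stood at 66.6 ± 0.369 FPKM in clone 1 (1.58 ± 0.08) and 64.5 ± 4.59 in clone 4 (1.54 ± 0.08), against 21.6 ± 0.493 in parental cells (SD, n = 2; adjusted p = 1.57e-08 and 1.57e-08). The survival gene BCL2A1, a target of the melanocyte regulator MITF, was lower (-2.91 ± 0.15 and -1.89 ± 0.15), as was MCL1 (-0.67 ± 0.13 and -0.46 ± 0.13; in clone 4 it did not pass without DMSO replicate 1, at -0.26, without parental DMSO replicate 2, at -0.34, or with the compared libraries alone). PMAIP1 (1.03 ± 0.09 and 0.91 ± 0.09), BAX (0.93 ± 0.17 and 0.92 ± 0.17), BBC3 (0.78 ± 0.23 and 0.93 ± 0.23) and CDKN1A (1.22 ± 0.12 and 1.31 ± 0.12) were higher, and BMF was lower (-0.48 ± 0.10 and -0.53 ± 0.10). BBC3 did not pass without parental DMSO replicate 2 (0.65 and 0.80), clone 1 DMSO replicate 2 (0.57) or clone 4 DMSO replicate 1 (0.77), nor without the filter in clone 1. With the compared libraries alone neither BBC3 nor BAX passed in clone 4. MYC was higher in clone 4 (0.31 ± 0.11, 0.23 and not passing without the 3 libraries that stand apart, nor under 5 other alternatives) and did not pass in clone 1 (0.21 ± 0.11) except after the length and GC correction (0.27). HEXIM1 did not pass (0.06 ± 0.09 and -0.19 ± 0.09), though it did in clone 4 without DMSO replicate 2 (-0.31). In clone 1, 1988 genes were higher and 2282 lower, and in clone 4 2608 and 2718. Of those that passed, 51.95% and 53.8% were higher after the length and GC correction.

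The largest differences upwards were the long noncoding RNA UCA1 (ENSG00000214049, chr19 15939757 to 15947130; 5.79 ± 0.14 and 6.63 ± 0.14) and the hemidesmosome integrin ITGB4 (ENSG00000132470, chr17 73717408 to 73753899; 5.49 ± 0.16 and 5.93 ± 0.16). The myeloid lectin CD33 (ENSG00000105383, chr19 51728320 to 51747115; 4.44 ± 0.14 and 4.64 ± 0.14) and GDA, guanine deaminase (ENSG00000119125, chr9 74729511 to 74872109; 4.30 ± 0.12 and 4.79 ± 0.12), followed. In clone 4 the largest included KRT81 (ENSG00000205426, chr12 52679697 to 52685318; 5.48 ± 0.20) and PAGE1 (ENSG00000068985, chrX 49452053 to 49460596; 5.06 ± 0.22), and in clone 1 GPR110 (3.74 ± 0.16). Downwards they included FDCSP (ENSG00000181617, chr4 71091788 to 71100969; -6.66 ± 0.19 and -6.02 ± 0.19) and the protease inhibitor SERPINA3 (ENSG00000196136, chr14 95058395 to 95090983; -6.26 ± 0.11 and -5.91 ± 0.11). Also among the 6 furthest down were HAPLN1, which links hyaluronan to proteoglycans (ENSG00000145681, chr5 82933624 to 83017432; -5.72 ± 0.19 and -6.29 ± 0.19), TFAP2B (-5.32 ± 0.11 and -5.59 ± 0.11) and RXRG (-5.12 ± 0.09 and -5.30 ± 0.09). S100A1 was among them in clone 1 (ENSG00000160678, chr1 153600402 to 153604513; -5.85 ± 0.21) and PTGES in clone 4 (-5.14 ± 0.12).

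Here a list member rose when it was higher in the clone. Of the p53 targets, 14 of 23 rose and 0 fell (16 and 0 alone, adjusted p = 4.45e-07, adjusted p = 0.0138 with an estimated correlation) in clone 1. In clone 4, 13 of 23 rose and 0 fell (16 and 0 alone, adjusted p = 7.56e-06, adjusted p = 0.0263 with an estimated correlation), with the p53-induced oxidoreductase TP53I3 at 1.16 ± 0.11 and 1.03 ± 0.11. In the list of dedifferentiated melanoma and receptor kinase genes, 13 of 23 rose and 3 fell (13 and 3 alone, adjusted p = 1.19e-06, adjusted p = 0.158 with an estimated correlation) in clone 1. In clone 4, 11 of 23 rose and 7 fell (11 and 7 alone, adjusted p = 0.0312, adjusted p = 0.407 with an estimated correlation), with the YAP targets ANKRD1 (3.15 ± 0.09 and 2.83 ± 0.09), CTGF (2.61 ± 0.08 and 2.49 ± 0.08) and CYR61 (2.27 ± 0.08 and 2.47 ± 0.08). Of the melanocyte lineage genes, 0 of 11 rose and 5 fell (0 and 5 alone, adjusted p = 0.0192, adjusted p = 0.158 with an estimated correlation) in clone 1. In clone 4, 1 of 11 rose and 6 fell (1 and 6 alone, adjusted p = 0.0303, adjusted p = 0.133 with an estimated correlation), with the endothelin receptor EDNRB at -1.20 ± 0.12 and -2.13 ± 0.12. In clone 1, E2F targets gave 10 of 30 higher and 1 lower (12 and 1 alone, adjusted p = 0.00148, adjusted p = 0.158 with an estimated correlation), and hypoxia and glycolysis genes 8 of 21 higher and 2 lower (8 and 2 alone, adjusted p = 0.0485, adjusted p = 0.158 with an estimated correlation). In clone 4, epithelial-mesenchymal genes gave 3 of 23 higher and 10 lower (3 and 11 alone, adjusted p = 0.00892, adjusted p = 0.133 with an estimated correlation), with the repressor SNAI2 at -2.24 ± 0.08 and the collagen COL6A2 at -3.44 ± 0.17. In the ATF4, NF-kB and interferon lists of clone 4, 9, 11 and 8 members were higher and 3, 5 and 3 lower (adjusted p = 0.0303, 0.0458 and 0.0458). With an estimated correlation these were adjusted p = 0.347, 0.133 and 0.133. With the compared libraries alone, 2119 genes passed in clone 1 and 1205 in clone 4, of 4270 and 5326 in the fit of all 18.

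The clones were compared with parental cells also untreated, at 0 h. BCL2L1 was at 58.8 ± 1.36 FPKM in clone 1 (1.79 ± 0.08) and 79.1 ± 1.60 in clone 4 (2.21 ± 0.08), against 16.3 ± 0.295 in parental cells (SD, n = 2). BCL2A1 (-3.23 ± 0.15 and -2.92 ± 0.15), MCL1 (-1.35 ± 0.13 and -0.98 ± 0.13), BMF (-0.41 ± 0.10 and -0.79 ± 0.10) and BID (-0.35 ± 0.12 and -0.99 ± 0.12) were lower. Higher were PMAIP1 (1.56 ± 0.09 and 1.21 ± 0.09), BBC3 (1.34 ± 0.23 and 1.32 ± 0.23), BAX (0.74 ± 0.17 and 0.79 ± 0.17) and CDKN1A (1.32 ± 0.12 and 1.42 ± 0.12). HEXIM1 (0.75 ± 0.09, adjusted p = 1.55e-05, and 0.76 ± 0.09, adjusted p = 1.16e-05), BRD2 (0.56 ± 0.11 and 0.90 ± 0.11) and MYC (0.54 ± 0.11 and 0.51 ± 0.11) were higher in both clones. In clone 1, 8142 genes passed, 35.5% of them higher, and in clone 4 8653, 40.4% of them higher. The median over all genes was -0.12 in clone 1 and -0.08 in clone 4. With quantile normalization it was 0.03 and 0.05, with 50.4% and 51.8% higher, so the changes are to be read against that shift, and BID (-0.21) and BMF (-0.18) in clone 1 did not pass with it, nor after the length and GC correction (both -0.15), BID also not when any 1 of 3 libraries was left out (-0.26 to -0.36).

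UCA1 was again the gene furthest up, at 420.1 ± 18.9 and 1142 ± 3.20 FPKM in the clones and 0.487 ± 0.236 in parental cells (8.15 ± 0.14 and 9.60 ± 0.14). CTGF (5.89 ± 0.08 and 6.76 ± 0.08), DKK1 (6.18 ± 0.14 and 6.31 ± 0.14) and the matrix glycoprotein THBS1 (ENSG00000137801, chr15 39873280 to 39891667; 4.95 ± 0.18 and 5.11 ± 0.18) were among the 6 furthest up in both. SPANXC (ENSG00000198573, chrX 140335596 to 140336629; 4.98 ± 0.17) and ITGB4 (5.24 ± 0.16) were among the 6 of clone 1, and KRT81 (5.33 ± 0.20) among those of clone 4. Among the 6 furthest down in both were HAPLN1 (-7.84 ± 0.19 and -8.39 ± 0.19), FDCSP (-7.34 ± 0.19 and -7.38 ± 0.19) and S100A1 (-7.43 ± 0.21 and -6.71 ± 0.21). The ion transport regulator FXYD3 (ENSG00000089356, chr19 35606732 to 35615228; -6.67 ± 0.23 and -6.67 ± 0.23) and KIAA1199, a hyaluronan-binding protein (ENSG00000103888, chr15 81071684 to 81244117; -6.48 ± 0.21 and -6.49 ± 0.21), were too. TFAP2B was among them in clone 1 (-6.46 ± 0.11) and SERPINA3 in clone 4 (-7.03 ± 0.11).

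Hypoxia and glycolysis genes were higher in the untreated clones: 18 of 21 rose and 2 fell (18 and 2 alone, adjusted p = 2.63e-13, adjusted p = 0.000781 with an estimated correlation) in clone 1. In clone 4, 16 of 21 rose and 2 fell (17 and 2 alone, adjusted p = 3.73e-07, adjusted p = 0.00826 with an estimated correlation). Adrenomedullin, ADM (4.07 ± 0.10 and 4.37 ± 0.10), the mitophagy gene BNIP3 (4.04 ± 0.09 and 3.33 ± 0.09), NDRG1 (3.32 ± 0.08 and 2.02 ± 0.08) and lactate dehydrogenase A, LDHA (2.65 ± 0.09 and 2.49 ± 0.09), were among them. Of 15 histone genes, 12 were higher in clone 1 and 13 in clone 4 (adjusted p = 1.51e-06 and 3.73e-06, with an estimated correlation 0.166 and 0.167). Also higher were the dedifferentiated melanoma, heat shock, multidrug and p53 lists in both, AP-1 in clone 1, and ATF4 and E2F in clone 4. Lower were melanocyte genes in both, NF-kB in clone 1 and epithelial-mesenchymal genes in clone 4 (adjusted p from 5.08e-06 to 0.0494). None of these passed with an estimated correlation.

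The untreated differences overlapped with those seen in DMSO, with which they share no library. Across 16935 genes the correlation was 0.747 in clone 1 and 0.794 in clone 4. They overlapped also with the CPI203 response of parental cells, again without a shared library. Of the 1006 genes changed at least 2-fold by CPI203 in parental cells, 906 (90.1%) lay in the CPI203 direction in untreated clone 1, with a median of 1.04, and 897 (89.2%) in untreated clone 4, with a median of 1.11. From 0 h to 6 h of DMSO the same genes moved the opposite way in the clones, by a median of -0.75 in clone 1 and -0.83 in clone 4, comparisons chosen after the data were seen. For genes chosen from the response of clone 1, so that no library is shared, the median in parental cells from 0 h to DMSO was -0.02 over 367 genes.

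**Figure D2:**
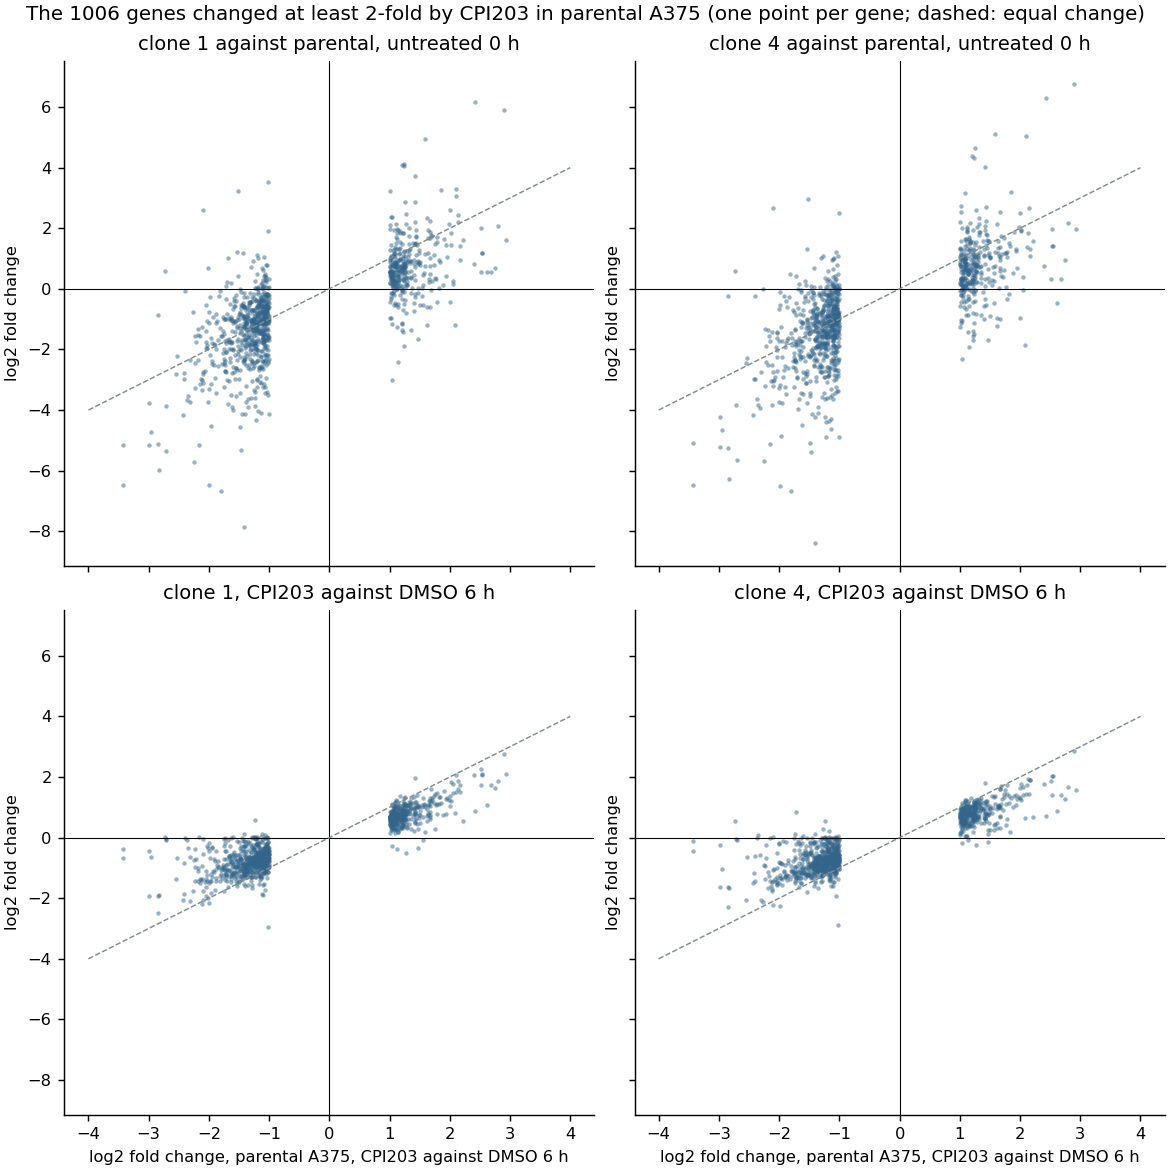
Log2 changes of the 1006 genes that CPI203 changed at least 2-fold in parental A375 cells (horizontal axes), against clone 1 and clone 4 relative to parental cells at 0 h untreated (vertical axes, upper panels) and the CPI203 effect in each clone (lower panels), with a dashed line of equal change. In the upper panels 90.1% and 89.2% of the genes lie in the same direction on both axes, and in the lower panels 98.01% and 97.7%.

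What changes in parental cells between 0 h and 6 h of DMSO served as the background for the treated groups. Of the E2F target genes, 26 of 30 rose and 0 fell (28 and 0 alone, adjusted p = 4.99e-20, adjusted p = 0.00081 with an estimated correlation), with the flap endonuclease FEN1 at 1.07 ± 0.09, CDC45 at 1.03 ± 0.11 and MCM5 at 0.92 ± 0.09 (n = 2). Heat shock genes gave 11 of 14 higher and 0 lower (11 and 0 alone, adjusted p = 2.28e-10, adjusted p = 0.00111 with an estimated correlation), with HSPA1A at 2.34 ± 0.13 (ENSG00000204389, chr6 31783291 to 31785717) and HSPH1 at 1.32 ± 0.09; HSPA1A and HSPA1B are near-identical copies. NF-kB and cytokine genes gave 0 of 24 higher and 13 lower (0 and 14 alone, adjusted p = 8.71e-10, adjusted p = 0.00081 with an estimated correlation), with the chemokine IL8 falling from 159 ± 0.540 to 33.6 ± 0.147 FPKM (ENSG00000169429, chr4 74606223 to 74609433; -2.21 ± 0.09) and ICAM1 at -1.48 ± 0.09. MYC targets gave 14 of 30 higher and 0 lower (15 and 0 alone, adjusted p = 2.95e-06, adjusted p = 0.00903 with an estimated correlation), with the transferrin receptor TFRC at 2.12 ± 0.22 (ENSG00000072274, chr3 195754054 to 195809060) and the nucleolar NOP56 at 0.81 ± 0.08.

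Among the genes that fell most from 0 h to DMSO were the hypoxia marker CA9 (ENSG00000107159, chr9 35673853 to 35681156; -3.18 ± 0.17), the thioredoxin inhibitor TXNIP (ENSG00000117289, chr1 145438469 to 145442635; -2.74 ± 0.08), NCAM2 (ENSG00000154654, chr21 22370633 to 22915650; -2.06 ± 0.29), RASA4 (ENSG00000105808, chr7 102220093 to 102257204; -1.92 ± 0.14) and the NF-kB target BIRC3 (ENSG00000023445, chr11 102188215 to 102210134; -1.86 ± 0.21). The small RNA genes RNU2-2P (ENSG00000222328, chr11 62609091 to 62609281; 3.14 ± 0.90) and SNORA73B (ENSG00000200087, chr1 28835071 to 28835274; 1.78 ± 0.53) rose too, at 26.3 ± 34.2 and 12.5 ± 12.1 FPKM, where parental DMSO replicate 1 is the library with the high share of small structured RNA, and without it they did not pass (1.11 and 0.70). BMF fell (-0.87 ± 0.10), BCL2L1 (0.39 ± 0.08) and BAX (0.62 ± 0.17) rose, and MYC (0.08 ± 0.11), HEXIM1 (0.14 ± 0.09), PMAIP1 (0.22 ± 0.09) and CDKN1A (0.31 ± 0.12) did not pass. After the length and GC correction PMAIP1 (0.24) and CDKN1A (0.19) passed. BAX did not when any 1 of 3 libraries was left out (0.47 to 0.67), and neither BAX nor BCL2L1 did with the compared libraries alone. In all, 3815 genes passed, 2068 higher and 1747 lower after DMSO. The share higher was 47.3% with median-ratio scaling. The count was 1274 with the compared libraries alone.

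In NOMO-1 leukaemia cells the effect of 24 h of CPI203 was compared first in parental cells. MYC fell from 68.4 ± 5.22 to 15.5 ± 1.39 FPKM (SD, n = 2; -2.08 ± 0.09, adjusted p = 3.96e-07), and HEXIM1 rose from 12.7 ± 1.55 to 52.1 ± 0.486 FPKM (1.96 ± 0.09). BCL2 fell from 19.4 ± 2.44 to 6.51 ± 0.776 FPKM (-1.44 ± 0.11), as did BCL2L1 (-0.71 ± 0.09), BID (-0.49 ± 0.09) and BAK1 (-0.57 ± 0.11). The BH3-only genes BMF (1.93 ± 0.12), PMAIP1 (1.17 ± 0.10), BCL2L11 (0.64 ± 0.13) and BBC3 (0.52 ± 0.13) rose, as did CDKN1A (1.55 ± 0.12), BRD2 (0.91 ± 0.07), MCL1 (0.54 ± 0.07) and BCL2A1 (0.47 ± 0.14), the last not passing without CPI203 replicate 1 (0.30) or DMSO replicate 2 (0.34), nor BBC3 without CPI203 replicate 2 (0.48). BRD3 (0.18 ± 0.09) and BAX (-0.20 ± 0.12) did not pass, though BRD3 did with quantile normalization (0.24) and BAX with the replicate block (-0.20). Of 16753 genes tested, 10049 passed, 4515 higher and 5534 lower. Of those that passed, 52.7% were higher with quantile normalization and 52.2% after the length and GC correction.

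Furthest down were MS4A6A (ENSG00000110077, chr11 59939081 to 59952139; -6.47 ± 0.09, from 171 ± 8.77 to 0.943 ± 0.118 FPKM) and the plasminogen activator inhibitor SERPINB2 (ENSG00000197632, chr18 61538926 to 61571124; -5.66 ± 0.10). The phagocyte oxidase CYBB (ENSG00000165168, chrX 37639264 to 37672714; -5.04 ± 0.11) and the chemokine receptor CCR2 (ENSG00000121807, chr3 46395225 to 46402419; -5.03 ± 0.12) were next. The amino acid transporter SLC38A5 (ENSG00000017483, chrX 48316920 to 48328644; -5.03 ± 0.13) and TGM5 (ENSG00000104055, chr15 43524793 to 43559055; -4.92 ± 0.12) followed. Among those furthest up were EFR3B (ENSG00000084710, chr2 25264999 to 25378243; 3.40 ± 0.10), HIST2H2BE (3.21 ± 0.10), HIST1H2BD (3.09 ± 0.11) and the paired copies HIST2H4A and HIST2H4B (3.16 ± 0.11 and 3.15 ± 0.11).

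Of the MYC family and target genes, 1 of 29 rose and 26 fell (1 and 26 alone, adjusted p = 1.12e-09, adjusted p = 0.297 with an estimated correlation), with the ribosome assembly factors RRS1 at -2.05 ± 0.09 and NOP16 at -2.23 ± 0.10. Myeloid differentiation markers gave 1 of 28 higher and 23 lower (1 and 23 alone, adjusted p = 8.05e-10, adjusted p = 0.292 with an estimated correlation), with MNDA at -3.56 ± 0.08, CEBPE at -3.94 ± 0.10 and the G-CSF receptor CSF3R at -2.52 ± 0.08. Histone genes gave 15 of 16 higher and 0 lower (15 and 0 alone, adjusted p = 1.15e-09, adjusted p = 0.292 with an estimated correlation). Of the p53 targets, 16 of 22 rose and 2 fell (16 and 2 alone, adjusted p = 0.00023, adjusted p = 0.329 with an estimated correlation), with TP53INP1 at 2.79 ± 0.12. E2F targets gave 1 of 30 higher and 20 lower (1 and 21 alone, adjusted p = 0.00023, adjusted p = 0.393 with an estimated correlation), and cholesterol genes 1 of 20 higher and 12 lower (1 and 12 alone, adjusted p = 0.0117, adjusted p = 0.292 with an estimated correlation). The MAPK list gave 10 of 15 higher and 3 lower (10 and 3 alone, adjusted p = 0.0114, adjusted p = 0.329 with an estimated correlation), with PHLDA1 at 2.64 ± 0.11 and DUSP6 at 1.79 ± 0.10. NOTCH and hedgehog genes gave 8 of 11 higher and 0 lower (8 and 0 alone, adjusted p = 0.0083, adjusted p = 0.292 with an estimated correlation), with the ligand JAG1 at 2.07 ± 0.11. The multidrug list gave 8 of 13 higher and 1 lower (8 and 1 alone, adjusted p = 0.0083, adjusted p = 0.33 with an estimated correlation), with NQO1 at 2.07 ± 0.14. In the MLL-fusion program, 14 of 22 rose and 5 fell (14 and 5 alone, adjusted p = 0.0472, adjusted p = 0.322 with an estimated correlation), with HOXA9 at 1.42 ± 0.08 and GFI1 at -1.75 ± 0.07. Lymphoid markers did not pass as a list: 0 of 9 rose and 3 fell (0 and 3 alone, adjusted p = 0.109).

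**Figure D3:**
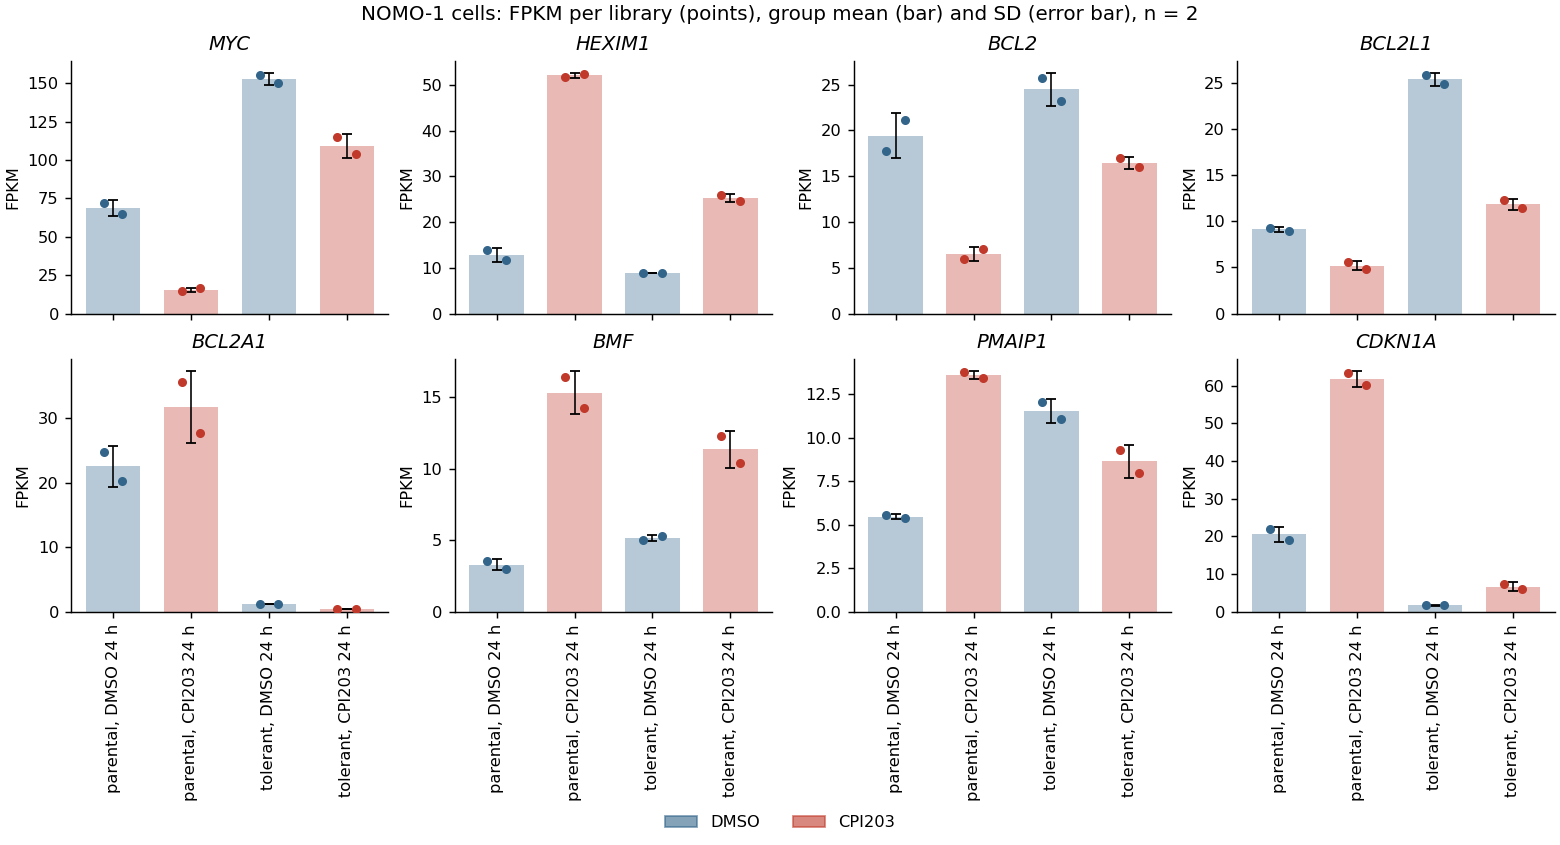
FPKM of MYC, HEXIM1, BCL2, BCL2L1, BCL2A1, BMF, PMAIP1 and CDKN1A in the 4 NOMO-1 groups (blue DMSO 24 h, red CPI203 24 h), with each library as a point, the mean as a bar and the SD of n = 2 as the error bar, on linear axes that start at 0. MYC averaged 68.4 FPKM with DMSO and 15.5 with CPI203 in parental cells, and 153 and 109 in tolerant cells.

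In tolerant NOMO-1 cells the same treatment lowered MYC from 153 ± 3.76 to 109 ± 7.71 FPKM (SD, n = 2; -0.48 ± 0.09, adjusted p = 0.0031). HEXIM1 (1.41 ± 0.09), BRD2 (0.40 ± 0.07), BMF (1.01 ± 0.12), MCL1 (0.69 ± 0.07) and CDKN1A (1.49 ± 0.12) rose. BCL2L1 (-1.04 ± 0.09), BCL2 (-0.54 ± 0.11), BCL2A1 (-0.66 ± 0.14) and PMAIP1 (-0.38 ± 0.10; not passing without DMSO replicate 1, at -0.33, or CPI203 replicate 2, at -0.28) fell. DHRS2 (3.73 ± 0.10), the intermediate filament VIM (ENSG00000026025, chr10 17270258 to 17279592; 2.86 ± 0.11) and KIAA0513 (ENSG00000135709, chr16 85061375 to 85127836; 2.40 ± 0.10) rose most. They were followed by LTB (ENSG00000227507, chr6 31548302 to 31550299; 2.34 ± 0.16), SAT1 (2.26 ± 0.12) and the myeloid regulator CEBPA (ENSG00000245848, chr19 33790840 to 33793470; 2.02 ± 0.17). The eosinophil granule gene PRG2 fell from 403 ± 3.02 to 4.84 ± 1.48 FPKM (ENSG00000186652, chr11 57154267 to 57158130; -6.14 ± 0.18), followed by hepatocyte growth factor, HGF (ENSG00000019991, chr7 81328322 to 81399754; -5.47 ± 0.17). Next were MS4A6A (-4.75 ± 0.09), SLC38A5 (-4.47 ± 0.13) and CEACAM6 (ENSG00000086548, chr19 42254885 to 42276113; -4.27 ± 0.16). Of 16753 genes 6560 passed, 3086 higher and 3474 lower. Of those that passed, 55.4% were higher with quantile normalization and 56.5% after the length and GC correction. Without DMSO replicate 1 or 2 the count was 4089 or 4079.

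Of the E2F targets, 18 of 30 rose and 1 fell (18 and 1 alone, adjusted p = 5.67e-05, adjusted p = 0.515 with an estimated correlation), with RRM2 at 0.99 ± 0.08. Mitotic genes gave 15 of 30 higher and 2 lower (16 and 2 alone, adjusted p = 0.000149, adjusted p = 0.524 with an estimated correlation), and histone genes 14 of 16 higher and 0 lower (15 and 0 alone, adjusted p = 1e-07, adjusted p = 0.335 with an estimated correlation). Interferon-response genes gave 3 of 23 higher and 15 lower (4 and 15 alone, adjusted p = 0.00128, adjusted p = 0.515 with an estimated correlation), with USP18 at -1.58 ± 0.10 and IRF7 at 1.54 ± 0.14. Cholesterol genes gave 0 of 20 higher and 13 lower (0 and 16 alone, adjusted p = 2.11e-05, adjusted p = 0.205 with an estimated correlation), with CYP51A1 at -1.27 ± 0.08. The ATF4 list had 12 lower members and the MYC list 15 (adjusted p = 5.67e-05 and 0.000333, and with an estimated correlation adjusted p = 0.515 and 0.515). Myeloid markers gave 5 of 28 higher and 18 lower (5 and 19 alone, adjusted p = 5.67e-05, adjusted p = 0.515 with an estimated correlation), with myeloperoxidase, MPO, at -4.25 ± 0.15 and IRF8 at 1.49 ± 0.09. Markers of other blood cell types moved with the drug as well: lymphoid markers gave 0 of 9 higher and 7 lower (0 and 7 alone, adjusted p = 1.79e-05, adjusted p = 0.323 with an estimated correlation), with NKG7 at -3.41 ± 0.10, and erythroid and megakaryocytic markers 0 of 5 higher and 4 lower (0 and 4 alone, adjusted p = 0.00169, adjusted p = 0.335 with an estimated correlation), with GATA1 at -1.42 ± 0.08.

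The difference between the CPI203 effects in tolerant and parental NOMO-1 cells was tested directly. It was 1.60 ± 0.13 for MYC (adjusted p = 5.44e-05; n = 2 per group) and 0.90 ± 0.16 for BCL2 (adjusted p = 0.00318), both of which fell less in tolerant cells. PMAIP1 (-1.56 ± 0.14, adjusted p = 8.37e-05) and BCL2A1 (-1.13 ± 0.19, adjusted p = 0.00251), which rose in parental cells and fell in tolerant cells, had lower effects in the latter. BMF (-0.92 ± 0.17, adjusted p = 0.00326), HEXIM1 (-0.55 ± 0.13, adjusted p = 0.0117, but not passing without parental CPI203 replicate 2) and BRD2 (-0.51 ± 0.09, adjusted p = 0.00332) rose less in tolerant cells. BCL2L1 (-0.33 ± 0.13), MCL1 (0.15 ± 0.10) and CDKN1A (-0.05 ± 0.16) did not pass, though BCL2L1 did with the replicate block (-0.33), median-ratio scaling (-0.40) and the length and GC correction (-0.42). In all 5322 genes differed, 2828 with a higher and 2494 with a lower effect in tolerant cells. With median-ratio scaling 45.8% of those that passed had a higher one. Leaving out either replicate of parental CPI203 or of tolerant DMSO gave counts from 3246 (tolerant DMSO replicate 2) to 3467 (parental CPI203 replicate 1).

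The highest differences were those of IL1RN, the interleukin 1 receptor antagonist (ENSG00000136689, chr2 113864791 to 113891593; 4.65 ± 0.14), CHI3L1 (ENSG00000133048, chr1 203148059 to 203155877; 4.28 ± 0.17) and NAPSB (ENSG00000131401, chr19 50837053 to 50848024; 4.07 ± 0.21). They were followed by SERPINB2 (4.06 ± 0.14), CCR2 (4.04 ± 0.17) and PTAFR (ENSG00000169403, chr1 28473677 to 28520447; 4.03 ± 0.13). IL1RN fell from 31.8 ± 0.294 to 1.53 ± 0.154 FPKM in parental cells and stood at 1.86 ± 0.0589 with DMSO and 4.55 ± 0.397 with CPI203 in tolerant cells. NAPSB and PTAFR stood at 0.283 and 0.519 FPKM with DMSO in tolerant cells, which left them little room to fall. Among the lowest were PRG2 (-5.22 ± 0.26), PPP1R1B (ENSG00000131771, chr17 37782993 to 37792879; -3.83 ± 0.17), IGLL1 (ENSG00000128322, chr22 23915312 to 23922495; -3.73 ± 0.21) and SEPP1 (ENSG00000250722, chr5 42799982 to 42887494; -3.56 ± 0.23), with PPP1R1B and IGLL1 at 0.427 and 0.0271 FPKM with DMSO in parental cells. VSTM1 (ENSG00000189068, chr19 54544079 to 54567207), also among the lowest, is listed at 0 in parental CPI203 libraries and stood at 19.1 ± 2.76 FPKM with DMSO in tolerant cells and 0.0548 ± 0.00470 with CPI203.

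For these lists a member rose when its effect was higher in tolerant cells. E2F targets gave 28 of 30 higher and 0 lower (30 and 0 alone, adjusted p = 1.36e-12, adjusted p = 0.273 with an estimated correlation), with MCM3 at 1.19 ± 0.10. MYC family and target genes gave 26 of 29 higher and 1 lower (26 and 1 alone, adjusted p = 4.84e-11, adjusted p = 0.273 with an estimated correlation), with RRS1 at 1.81 ± 0.13. Myeloid markers gave 17 of 28 higher and 4 lower (17 and 5 alone, adjusted p = 3.06e-06, adjusted p = 0.298 with an estimated correlation), with IRF8 at 3.12 ± 0.13 and CSF3R at 2.54 ± 0.11. Histone genes gave 1 of 16 higher and 10 lower (1 and 10 alone, adjusted p = 0.000104, adjusted p = 0.298 with an estimated correlation), and interferon-response genes 1 of 23 higher and 11 lower (1 and 11 alone, adjusted p = 0.000144, adjusted p = 0.298 with an estimated correlation). The BH3-only list gave 0 of 8 higher and 4 lower (0 and 4 alone, adjusted p = 0.0066, adjusted p = 0.413 with an estimated correlation), with BIK at -1.67 ± 0.17. The MAPK list gave 2 of 15 higher and 9 lower (2 and 9 alone, adjusted p = 0.000465, adjusted p = 0.273 with an estimated correlation).

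Tolerant and parental NOMO-1 cells were also compared in DMSO. MYC was higher in tolerant cells, at 153 ± 3.76 against 68.4 ± 5.22 FPKM (SD, n = 2; 1.15 ± 0.09, adjusted p = 5.26e-06). BCL2L1 was higher (25.4 ± 0.672 against 9.10 ± 0.222 FPKM; 1.38 ± 0.09), as were BRD3 (0.30 ± 0.09; 0.24 and not passing without tolerant DMSO replicate 1), PMAIP1 (0.96 ± 0.10), BMF (0.52 ± 0.12) and BCL2 (0.32 ± 0.11), the last not passing without parental DMSO replicate 1 (0.20) or tolerant DMSO replicates 1 or 2 (0.25 and 0.39), nor without the filter. CDKN1A was lower, at 1.71 ± 0.105 against 20.5 ± 2.04 FPKM (-2.99 ± 0.12), as were BCL2A1 (-3.44 ± 0.14), MCL1 (-0.75 ± 0.07) and BBC3 (-0.77 ± 0.13). Also lower were BAK1 (-0.72 ± 0.11), BAX (-0.60 ± 0.12), BRD2 (-0.53 ± 0.07), HEXIM1 (-0.46 ± 0.09) and BID (-0.41 ± 0.09). In all 10796 genes passed, 4725 higher and 6071 lower. The median over all genes was -0.07, and 0.04 with quantile normalization, under which 52.9% of the genes that passed were higher in place of 43.8%.

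HLA class II genes (not a fixed list) were among the 6 furthest down in tolerant cells. HLA-DRA was at 0.0611 ± 0.0576 FPKM there and 488 ± 28.8 in parental cells (ENSG00000204287, chr6 32407619 to 32412823; -8.85 ± 0.09). CD74, the invariant chain, was at 0.925 ± 0.405 and 776 ± 72.5 (ENSG00000019582, chr5 149781200 to 149792492; -8.67 ± 0.14), and HLA-DPA1 at 0.0280 ± 0.0397 and 151 ± 14.4 (ENSG00000231389, chr6 33032346 to 33048552; -7.21 ± 0.11). HLA-DRB1 (ENSG00000196126, chr6 32546546 to 32557625; -6.61 ± 0.12), RNASE6 (ENSG00000169413, chr14 21249210 to 21250626; -6.90 ± 0.14) and HHLA2 (ENSG00000114455, chr3 108015376 to 108097132; -6.57 ± 0.11) completed the 6. CIITA, the regulator that switches on class II genes, was at 0.269 ± 0.0428 and 9.29 ± 1.19 FPKM, a gene chosen after the values were seen. Furthest up was the matrix protein SPARC, at 222 ± 10.3 against 0.0957 ± 0.0351 FPKM (ENSG00000113140, chr5 151040657 to 151066726; 7.67 ± 0.09). The homeobox gene HOXD13 was at 78.5 ± 0.153 against 0.148 ± 0.0236 FPKM (ENSG00000128714, chr2 176957619 to 176960666; 6.11 ± 0.09), and C19orf77 at 164 ± 9.62 against 1.71 ± 0.199 (ENSG00000095932, chr19 3474405 to 3480540; 5.92 ± 0.10). The neutrophil defensin copies DEFA3 (7.56 ± 0.15) and DEFA1B (6.33 ± 0.15) were higher, and DEFA1 was listed at 0 in parental DMSO libraries and at 56.3 ± 8.06 FPKM in tolerant ones. These copies are near-identical, so their single values are uncertain.

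The MLL-fusion and leukaemia stem cell program had 5 of 22 higher and 13 lower (5 and 15 alone, adjusted p = 0.0129, adjusted p = 0.434 with an estimated correlation) in tolerant cells. HOXA9 stood at 0.0164 ± 0.0231 FPKM in tolerant and 85.5 ± 3.91 in parental cells (ENSG00000078399, chr7 27202054 to 27210117; -6.41 ± 0.08). HOXA10 stood at 0.00871 ± 0.0123 and 49.6 ± 3.88 (ENSG00000253293, chr7 27210210 to 27219880; -5.65 ± 0.09). HOXA3 and HOXA7 were listed at 0 in the tolerant DMSO libraries and at 16.7 ± 0.499 and 18.6 ± 1.14 FPKM in parental ones. On either side of the cluster, SKAP2 was at 3.89 and 40.04 FPKM and HIBADH at 12.6 and 13.2 FPKM in tolerant and parental cells, neighbours chosen after the values were seen. Cholesterol genes gave 19 of 20 higher and 0 lower (19 and 1 alone, adjusted p = 1.46e-08, adjusted p = 0.0758 with an estimated correlation), with HMGCS1 at 2.19 ± 0.08. The ATF4 list gave 17 of 20 higher and 0 lower (17 and 0 alone, adjusted p = 6.53e-07, adjusted p = 0.586 with an estimated correlation), with TRIB3 at 3.14 ± 0.11. Histone genes gave 1 of 16 higher and 15 lower (1 and 15 alone, adjusted p = 7.05e-05, adjusted p = 0.586 with an estimated correlation), with HIST1H1C at -4.15 ± 0.11. MYC family and target genes gave 19 of 29 higher and 1 lower (20 and 1 alone, adjusted p = 0.000385, adjusted p = 0.586 with an estimated correlation), and p53 targets 2 of 22 higher and 16 lower (2 and 16 alone, adjusted p = 0.0129, adjusted p = 0.586 with an estimated correlation). Myeloid markers went both ways: 8 of 28 rose and 17 fell (8 and 17 alone, adjusted p = 0.237), with lysozyme, LYZ, at -4.98 ± 0.08 and CSF3R at 3.28 ± 0.08.

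**Figure D4:**
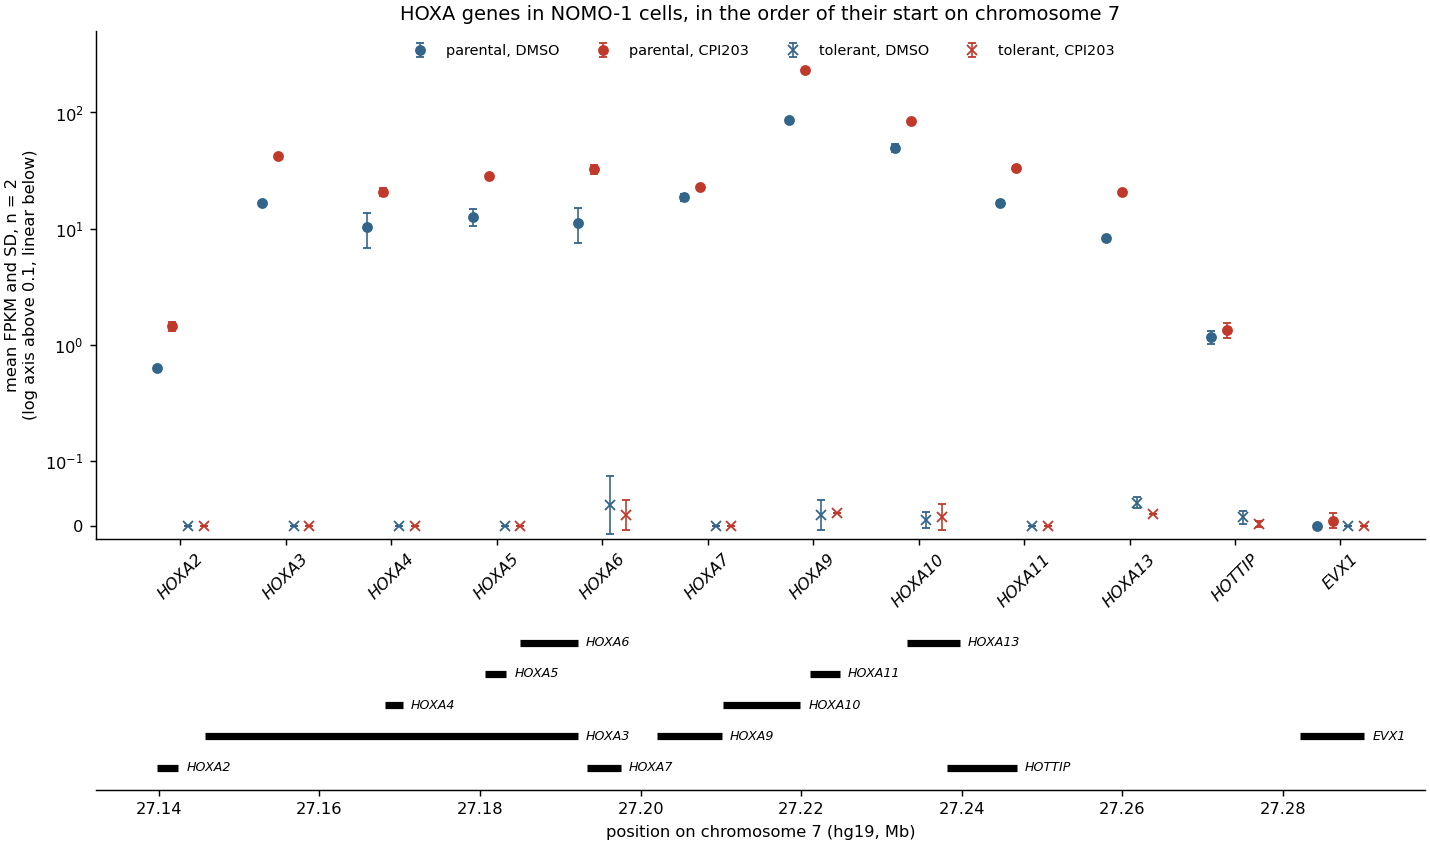
Mean FPKM ± SD (n = 2) of genes of the HOXA cluster from HOXA2 to EVX1 in the 4 NOMO-1 groups, on a log axis above 0.1 and a linear one below, with a map of the genes on chromosome 7 (hg19, Mb). HOXA9 averaged 85.5 FPKM with DMSO and 231 with CPI203 in parental cells, and 0.0164 and 0.0192 in tolerant cells.

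Across the lines, which differ in duration of treatment, the CPI203 response of parental NOMO-1 cells correlated with that of parental A375 cells over 14335 genes (Pearson r = 0.552; genes are not independent replicates). In both, 1530 genes rose and 1829 fell, where independence would give 638.3 and 909.5. The 2109 genes that changed at least 2-fold in parental NOMO-1 cells had a median absolute change of 1.34 there and moved in that direction by a median of 0.56 in tolerant cells. Tolerant-parental differences in DMSO did not run in parallel between the lines: r was 0.0427 for NOMO-1 with A375 clone 1 and -0.00940 with clone 4. In DMSO both clones and tolerant NOMO-1 cells had higher BCL2L1 and PMAIP1 and lower BCL2A1 and MCL1 than parental cells. BAX, BBC3 and CDKN1A were higher in the clones and lower in tolerant NOMO-1 cells.

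**Figure D5:**
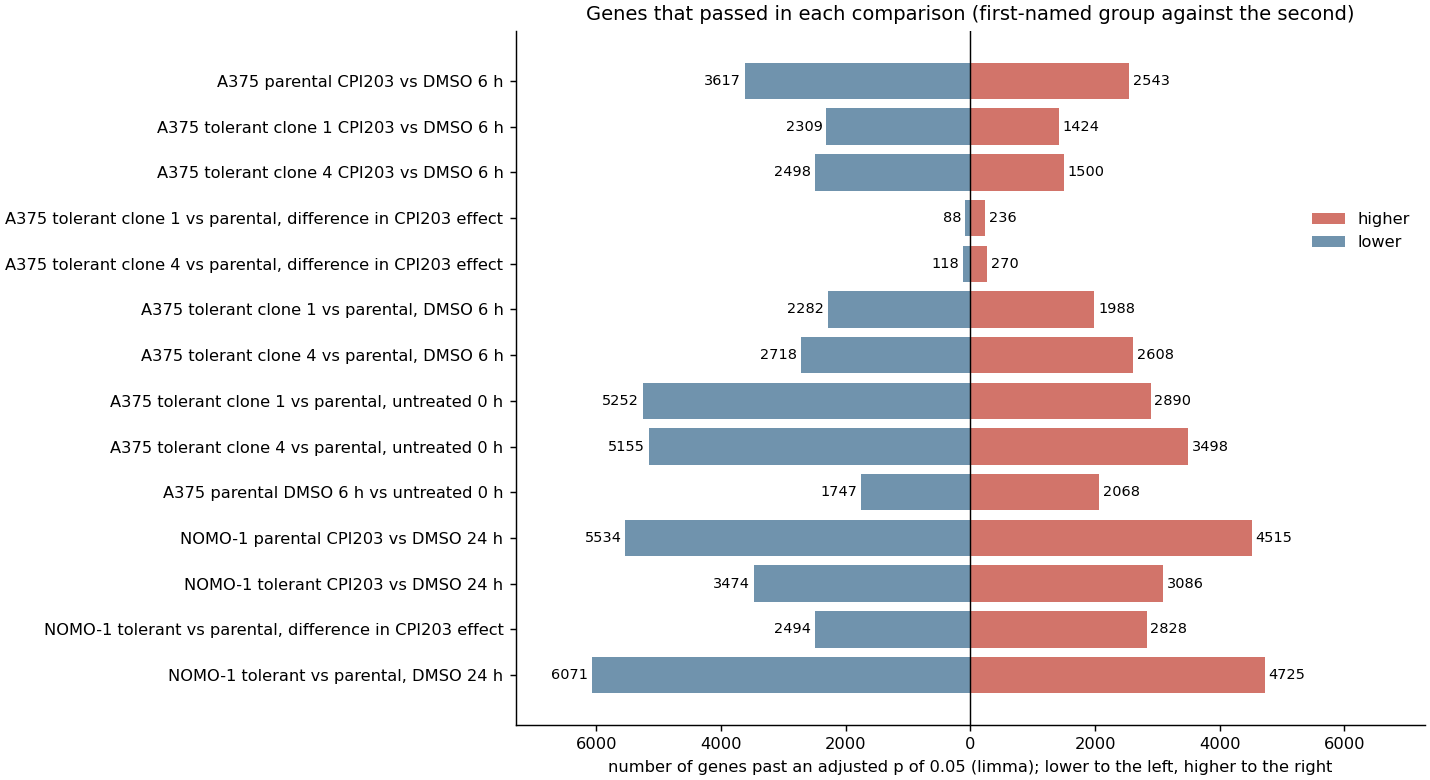
Number of genes past an adjusted p of 0.05 in each of the 14 planned comparisons, as horizontal bars from 0 (lower genes to the left, higher genes to the right). The numbers run from 324 for the difference in CPI203 effect of A375 clone 1 to 10796 for tolerant against parental NOMO-1 cells in DMSO.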

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

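The tests on the change of the clones from 0 h to DMSO and on the 9p21 genes were chosen only after the result was seen. In 17 results the effect of CPI203 differed between tolerant and parental cells by the test of the difference itself. For A375 clone 1, 324 genes differed, among them MYC (0.92), BCL2L1 (0.71), PMAIP1 (-1.0) and CDKN1A (-0.93), the last not passing when any 1 of 5 libraries was left out. For clone 4, 388 genes differed, among them BCL2L1 (0.59), PMAIP1 (-1.18) and CDKN1A (-1.04), though these 3 did not pass with the compared libraries alone. For NOMO-1, 5322 genes differed, among them MYC (1.60), HEXIM1 (-0.55), BRD2 (-0.51), BCL2 (0.90), BCL2A1 (-1.13), BMF (-0.92) and PMAIP1 (-1.56).

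Untreated clone libraries resembled CPI203-treated parental cells. If these libraries held parental cells, as 1 of their labels says, genes that set the clones apart in DMSO and that CPI203 barely moves would show little difference at 0 h, but the slope of the untreated on the DMSO difference was 1.069 in clone 4 and 1.077 in clone 1, which argues against it. A lasting difference of the clones that is independent of medium and handling is argued against by the change of the 1006 CPI203 genes from 0 h to DMSO, a median of -0.746 in clone 1 and -0.832 in clone 4 against the CPI203 direction. CPI203 still acting in the clones at harvest was left open. Genes moved at least 2-fold by CPI203 in both NOMO-1 populations had medians of 0.877 and 0.883 that way in untreated clones 4 and 1. Their median was 0.798 with CPI203 in parental A375 cells, so this repeats the resemblance. Whether the 0 h clone cultures held the drug is not stated, and a difference in oxygen or density, for which the higher hypoxia genes leave room, was not tested.

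The 3 A375 libraries that stand apart from their replicates were parental DMSO replicate 1, clone 4 DMSO replicate 1 and clone 4 CPI203 replicate 2. A swap between the last pair is argued against: over genes that CPI203 changed in clone 1, DMSO replicate 1 lay 0.0169 of the way from the other DMSO library to the other CPI203 library, and CPI203 replicate 2 lay 1.02 of that way. A bias in transcript length and GC content cannot be told apart from other sources: removing each library's trend took 25.3% off the replicate difference for clone 4 DMSO, 26.6% for parental DMSO and 34.5% for clone 4 CPI203, between the bounds set for a cause and against one. Of the other 6 pairs, 3 lost 22.2% to 31.1%, and after the correction the 3 pairs still stood at a median difference of 0.151 to 0.219 against 0.0596 to 0.0796 for the others. No biological explanation was tested.

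In NOMO-1, 55 genes were at 5 FPKM or more in all 4 libraries of one population and at 0.1 or less in all 4 of the other: 44 were on in parental and 11 in tolerant cells, against 6 and 5 such genes between parental A375 cells and clones 1 and 4, and 369 between parental A375 and parental NOMO-1 cells. MTAP, CDKN2A and CDKN2B (9p21) were near 0 in both NOMO-1 populations, with 0 of 3 at 1 FPKM in tolerant libraries (highest 0.0528). Selection or differentiation within the line would give that, as would another line with this common deletion, so genotypes are needed. CDKN2B was as low in A375 cells (at most 0.0547 FPKM). MEIS1 and neighbouring HOXA and HLA class II genes are among the 55, but clustering was not tested.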

How the results depend on the processing

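The omission of 3 libraries, the length and GC correction, and the comparisons of DMSO with untreated clones were chosen after seeing the data. Named genes, many chosen for large changes here, gave 5291 values under the alternatives. Of these 5170 kept direction and side of the threshold, 94 no longer passed, 27 newly passed and 0 changed direction. Of 372 gene-by-comparison results 318 held throughout, and counts over all genes varied more. The difference of effect for MYC in clone 4 passed only after the length and GC correction (0.55). The difference of effect for HEXIM1 passed with quantile normalization (-0.54 in clone 1, -0.55 in clone 4), after the length and GC correction (-0.52 and -0.49), without the 3 libraries (-0.49 and -0.61) and in clone 4 without its DMSO replicate 1 (-0.60). That for BCL2L1 in clone 4 did not pass without the 3 libraries (0.45), nor without parental CPI203 replicate 2 (0.50), parental DMSO replicate 1 (0.57) or clone 4 CPI203 replicate 2 (0.55). That for CDKN1A in clone 1 did not pass without some single libraries (-0.84 to -0.98). RNU2-2P and SNORA73B did not pass without untreated replicate 1 (3.37 and 1.59) or 2 (2.92 and 1.97). In all, leaving out 1 library ended the call for 52 of 1712 values. Of 110 list calls in planned comparisons, 13 passed with an estimated correlation, 98 with quantile normalization and 106 with median-ratio scaling, none in the opposite direction. Unknown depth keeps counting error from being separated from other spread. The cause was not tested for any change below except where fewer genes or libraries enter.

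With an absolute log2 change of at least 1, CPI203 changed 1006 genes in parental A375 cells, 367 in clone 1, 379 in clone 4, 2109 in parental NOMO-1 cells and 1065 in tolerant ones, and its effect differed for 115 (clone 1), 155 (clone 4) and 1338 (NOMO-1). Tolerant and parental cells in DMSO then differed in 956 (clone 1), 1194 (clone 4) and 3342 (NOMO-1) genes, untreated ones in 2434 and 2755 (clones 1 and 4), and parental DMSO from untreated A375 cells in 243. With the compared libraries alone the counts were 3977 for CPI203 in parental A375 cells, 6717 in clone 1 and 24 in clone 4, 163 and 41 for the differences of effect in clones 1 and 4, 2119 and 1205 for clones 1 and 4 in DMSO, and 1274 for parental DMSO against untreated cells. The differences of effect in clones 1 and 4 gave 144 and 172 genes with a pseudocount of 0.1, 203 and 223 with the filter at 5 FPKM, and 498 and 641 after the length and GC correction. Without the 3 libraries, clone 1 gave 7162 genes for CPI203 and 761 for the difference of effect.

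When each replicate was left out in turn, the sample left alone in its group was assumed to vary like the other groups. Counts for CPI203 ran from 4104 (without parental CPI203 replicate 1) to 6350 in parental A375 cells and from 1998 to 2162 in clone 1, with 2162 and 2102 without DMSO replicates 1 and 2 and 2048 and 1998 without CPI203 replicates 1 and 2. In clone 4 they ran from 2471 (without CPI203 replicate 1) to 6234 (without DMSO replicate 2), in parental NOMO-1 cells from 7632 to 10403, and in tolerant ones from 4079 to 4999 (4089 and 4079 without DMSO replicates 1 and 2). The clone 1 difference of effect ran from 154 to 303: 156 and 175 without parental CPI203 replicates 1 and 2, 166 and 189 without clone 1 DMSO replicates 1 and 2, and 154 and 160 without its CPI203 replicates. That of clone 4 ran from 219 to 597 (219 and 225 without parental CPI203 replicates 1 and 2, 597 without clone 4 DMSO replicate 2), and that of NOMO-1 from 3246 to 7101 (3467 and 3453 without parental CPI203 replicates 1 and 2, 3334 and 3246 without tolerant DMSO replicates 1 and 2). Clones 1 and 4 in DMSO gave 2870 to 4140 and 3967 to 7175 genes, and untreated 6273 to 6663 and 6784 to 7031. Tolerant against parental NOMO-1 cells in DMSO gave 8676 to 11000 genes. Parental DMSO against untreated A375 cells gave 1708 to 4256 (1778 and 1708 without untreated replicates 1 and 2, 2029 without DMSO replicate 1).

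With the replicate number as a block, counts were 6021 for CPI203 in parental A375 cells and 3847 in clone 4. In NOMO-1 they were 10913 in parental and 7715 in tolerant cells, and 6804 for the difference of effect. Across genes, deviations of equally numbered libraries correlated at a median of 0.0356 (-0.729 to 0.721) over 36 pairs of A375 groups. Over 6 NOMO-1 pairs it was 0.179 (0.0184 to 0.386).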

Other observations

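The test on chromosome 13 and the choice of the regions named here were made only after the result was seen. Between 0 h and 6 h of DMSO, 5127 genes rose and 2183 fell in clone 1, and 4790 and 2196 in clone 4 (n = 2), and with the compared libraries alone 1845 and 770 in clone 4. The median over all genes was 0.15 and 0.11, and 50.4% and 50.2% of the genes that passed rose with median-ratio scaling. HEXIM1 fell (-0.55 ± 0.09 and -0.81 ± 0.09), as did CTGF (-1.97 ± 0.08 and -2.96 ± 0.08). PMAIP1 fell in clone 1 (-0.32 ± 0.09; -0.26 and not passing without untreated replicate 1), and in clone 4 (-0.09 ± 0.09) it passed only with median-ratio scaling (-0.23) and the length and GC correction (-0.20). Hypoxia and glycolysis genes gave 0 of 21 higher and 21 lower (0 and 21 alone, adjusted p = 1.53e-23, adjusted p = 7.44e-05 with an estimated correlation) in clone 1, and 0 of 21 higher and 20 lower (0 and 20 alone, adjusted p = 1.08e-17, adjusted p = 0.000246 with an estimated correlation) in clone 4.

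Genes of chromosome 1 lay lower in clone 1 than in parental cells, by a median of -0.33 against the other chromosomes in DMSO. Loss of part of a chromosome copy may account for this: in the untreated libraries, which share none with the DMSO contrast, the median over 1114 genes was -0.34. Genes between 0 and 70 Mb on chromosome 1 were at a median of -0.45 in clone 1 and -0.47 in clone 4 in DMSO (415 genes), and those from 70 to 250 Mb at -0.22 and 0.041 (699 genes). The shift between 0 and 70 Mb was thus not particular to clone 1, and both clones are set against the same parental libraries. A shift of this kind from a change in regulation of neighbouring genes was not tested, and no DNA was measured.

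Genes of chromosome 13 lay lower in clone 4, by a median of -0.38 against the other chromosomes in DMSO and -0.33 untreated (202 genes), for which loss of part of a chromosome copy may likewise account.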
